A study of Saccharomyces cerevisiae with 76 samples.

How the data were processed

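Poly(A) sites were mapped by 3′ READS in 76 libraries of budding yeast, 2 biological replicates for each of 38 groups. The groups are 32 deletion strains of JGY2000, the parent used for anchor-away depletion; the nhp6a nhp6b deletion strain in BY4741; Dbp2 and Top2 anchor-away strains treated with 1 µM rapamycin for 1 h, the only groups given it; BY4741; and 2 pairs of JGY2000 whose titles carry the years 2018 and 2022. Cultures were grown in rich medium at 30 °C. The labels date no other strain.

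The submitters' processing notes name Bowtie for mapping; its version and the genome build are not given in the sources used here. Each deposited position value is the percent of the gene's highest position, for the 400 nt past the stop codon. The deposited read columns (ORF sum, window total and highest position) hold a signal, read numbers multiplied by 1 factor per library. The authors' weighted average isoform location is another deposited unit, nt past the stop codon. Files that pool both replicates (38) were not used. The dom34 files merge 2 library sets per replicate, per the file names.

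Whole reads were recovered by dividing the deposited read columns by the step of each library. Within a tolerance of 0.1, at least 99.5 percent of window totals per library and 100 percent of highest positions came out whole. ORF and window reads then summed to 0.478 M (pfd1 A), 1.43 M (pfd1 B), 4.60 M (replicate B of the libraries labelled hbs1 ski1) and up to 46.7 M, with a median of 21.5 M. The scaled totals in the deposited files ran from 21.8 to 24.3 M. PCR copies were not told apart from independent molecules, so counting error alone understates the spread. Calls rest on replicates, and no binomial interval was used.

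For each gene and library the mean poly(A) position was the sum of position times value over positions 1 to 400, divided by the sum of values. It differed from the authors' location by at most 0.499 nt. Of 6198 features, 5798 are ORFs, 4864 had a profile in all libraries and 3927 had on average at least 20 positions above 0 and were tested. A strain's own deleted gene was set missing. Locus tags were matched to RefSeq genes for 5795 ORFs, and 5787 of these had the coordinates of the R64 table. The chromosomes and stop codons printed here are those of the deposited data. The nearest ORF past the stop codon was convergent for 2098 tested genes and tandem for 1829.

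Samples were grouped by strain as labelled. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 76 libraries, with robust empirical Bayes moderation. Each of 34 strains and BY4741 was compared with both JGY2000 pairs, the larger p was kept (1 if the signs differed), and Benjamini-Hochberg adjustment over genes was held to 0.05. The shift is the strain mean minus the mean of the JGY2000 pair means; a negative value lies nearer the stop codon. The nhp6a nhp6b strain was compared with BY4741, JGY2000 2022 with 2018, and Dbp2 with Top2 anchor-away, each in 1 contrast. fry tested whether all genes move on balance one way, adjusted over 35 strains. camera tested 15 of 16 fixed gene lists; intron-containing genes could not be listed from the table used here. Shifts of 14 preset strain pairs were correlated across 3896 genes, 1 strain against the 2018 pair and the other against the 2022 pair and then the reverse, so that no control was shared. The mean correlation was set against 100000 permutations of the strain names, one-sided.

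These tests, the gene lists, the strain pairs, the other settings to try and the rule for naming genes were fixed before the data were examined. The rule ranks strains by called genes, with nhp6a nhp6b ranked by its 1 contrast. It names up to 10 genes each way for the 4 highest strains and 1 each way down to rank 12, the largest shifts among called genes whose strain libraries both lie beyond all control libraries. It adds the 10 genes called in most strains and the deleted or depleted genes.

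The list tests were run 3 ways. camera with an estimated correlation came first and camera with a preset correlation of 0.01 was fixed with it as the other setting. Fisher's exact test of called genes, 1050 tests over lists, strains and directions, was added after camera had called no combination; genes are not independent, so its p-values are too small to an unknown degree. Reads per gene were tested with edgeR 4.0.16 (quasi-likelihood, at least 10 reads, the same rule of both pairs), a test also chosen after seeing the data. Strains were split into 2 blocks by average linkage on their shift correlations, and names were permuted within the blocks, again after seeing the data. So were variance weights per group, a filter of at least 50 reads in every compared library, and a fit without the eaf3 and pfd1 libraries. Settings fixed in advance were the median position, positions 1 to 300, positions below 2 percent of the highest set to 0, no filter, at least 50 positions, 1 contrast against the mean of the 4 JGY2000 libraries, a replicate block, and leaving out each replicate. Extraction used Python 3.11.15 with numpy 2.4.6, and plots used matplotlib 3.10.9.

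The fit was tested on simulated data built on the gcn5 comparison with 3896 genes. limma called 28, 50, 80 and 94 percent of genes shifted by 10, 20, 40 and 80 nt and no unshifted gene. The simulated strains lay midway between both JGY2000 pairs, so the rate of false calls for a strain nearer either pair stays unknown. They also shared the pooled spread of each gene, so the rate in groups with a larger spread stays unknown too. edgeR called 4, 22, 100 and 100 percent of genes changed 1.5, 2, 4 and 8-fold among 5559 genes and no unchanged gene. That simulation gave both JGY2000 pairs the same means and all genes and groups 1 fixed dispersion. The real pairs differ in reads in 2565 genes, so the rate of false calls in the data stays unknown. A shared shift given to a strain pair came back as a correlation of 0.384, rank 1 of all pairs. In a simulated rai1 strain with every gene moved by 10 nt, camera called 5 unshifted lists, and in all other simulated strains it called 0, so a list call in a strain whose genes all move needs care.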

Results

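Where yeast mRNAs end was measured by 3′ READS, a method that sequences the last nucleotides before the poly(A) tail, in 76 libraries from 38 groups of 2 biological replicates each. The strains lack or deplete factors of chromatin, transcription, RNA decay and RNA processing. The median library held 21.5 M reads in ORFs and the 400 nt past them. The pfd1 libraries were far thinner, at 0.478 and 1.43 M reads, and the deepest library held 46.7 M. A gene's mean poly(A) position in nt past its stop codon was compared in 3927 genes.

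Deleted genes were read first as a check of the strain labels. Of 36 deleted genes, 34 had ORF or window reads below those of all control libraries in both libraries of their strain. ELF1, a transcription elongation factor gene, had 0 ORF reads in both elf1 libraries. PFD1, encoding a prefoldin subunit, had 0 ORF reads in the thin pfd1 libraries, but some controls also had 0. By ORF reads alone 28 of 36 passed. NHP6A stood at 0.618 and 0.540 cpm inside its ORF in its strain, above the 0.0673 to 0.294 of the controls, but at 11.5 and 9.65 cpm in its window against 328 to 374. SUB1 ORF reads, at 0.478 and 0.261 cpm in sub1, lay within the 0.196 to 1.53 of the controls. XRN1, the cytoplasmic exonuclease gene also called SKI1, stood at 31.9 and 33.3 cpm inside its ORF, counts scaled to library size, in the libraries labelled hbs1 ski1, against 12.8 to 28.0 in JGY2000. SKI7, encoding an exosome adaptor absent from that label, was at 0 and 0.217 cpm against 2.80 to 9.21. HBS1, a ribosome rescue factor gene, had 0 ORF reads there. DBP2 and TOP2 mRNA says nothing about anchor-away, which removes the protein from the nucleus; DBP2 was at 14.6 and 11.6 cpm inside the ORF in its strain (controls 11.7 to 28.8) and TOP2 at 11.4 and 17.1 in its strain (controls 15.3 to 45.0). The genotype label of the Top2 strain names DBP2-FRB, as that of the Dbp2 strain does. TOP2 window reads stood at 27.6 and 28.3 cpm in the Top2 strain and 75.7 and 59.6 in the Dbp2 strain, against 52.1 to 64.7 in the controls. DBP2 window reads stood at 72.9 and 99.7 cpm in the Dbp2 strain, against 121 to 492, and in the Top2 strain at 50.5 and 240, below the controls in replicate A alone. These reads differ the way the strain names say, with that exception, but do not measure the proteins.

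The parent itself sets the background. The JGY2000 2022 pair differed from the 2018 pair in 1361 genes, 1004 downstream and 357 upstream, with a median shift of 2.76 nt over all genes; without replicate A of the 2022 pair the count was 881. For this reason a strain's gene had to be called against both pairs. BY4741, a common laboratory strain, differed from both pairs in 16 genes, all downstream, and in 6 without BY4741 replicate A, 2 without replicate B, 2 without JGY2000 2018 replicate A and 8 without its replicate B. In 34 simulated strains with no change, no gene was called. These strains were placed midway between the 2018 and 2022 pairs. Shifts against the 2 pairs then tend to opposite signs, which the rule does not call. The simulation thus cannot say how often an unchanged strain nearer either pair would be called. It also gave every strain the same spread per gene, pooled over groups. The real groups differ, with variance weights, lower where replicates differ more, from 0.0505 in eaf3 to 5.21 in syc1. False calls in noisier groups such as eaf3, snf2 and gcn5 were thus not simulated. The 32 deletion strains of JGY2000 fell into 2 blocks by the correlation of their shifts. On the line from the 2018 to the 2022 pair 19 strains lay 51 to 112 percent of the way, and 13 strains, among them rrp6, chd1, sub1 and the libraries labelled hbs1 ski1, lay 1.28 to 34.2 percent of the way. The labels give no dates that would say whether the blocks are library batches.

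The count of called genes ranged from 0 to 1341 per strain. The comparison asks which factors set where transcripts end. Loss of Eaf3, a subunit shared by a histone acetyltransferase and a histone deacetylase complex, shifted 1341 genes, deletion of both HMGB protein genes NHP6A and NHP6B 1286 genes, and Dbp2 depletion 1259. The nhp6a nhp6b count comes from 1 contrast with BY4741, an easier rule than that of both pairs: with 1 contrast against the 4 JGY2000 libraries 12 strains exceeded 1286, eaf3 with 2307 and Dbp2 depletion with 2231 at the top. Loss of the acetyltransferase Gcn5 shifted 1058 genes and loss of the remodelling ATPase Snf2 1002. The order depends on the setting: with variance weights air1 air2 had 949 calls, rai1 784 and rrp6 731, against 576 in gcn5, 444 in snf2 and 148 in eaf3, and with 1 contrast air1 air2 had 2062, gcn5 2019 and snf2 2006. At the other end, Sub1, a transcription coactivator, gave 0 calls with limma, where 31 genes had an unadjusted p below 0.05; variance weights gave 4, leaving out JGY2000 2018 replicate B 1, the median position 12 and 1 contrast against the 4 JGY2000 libraries 402.

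**Figure D1:**
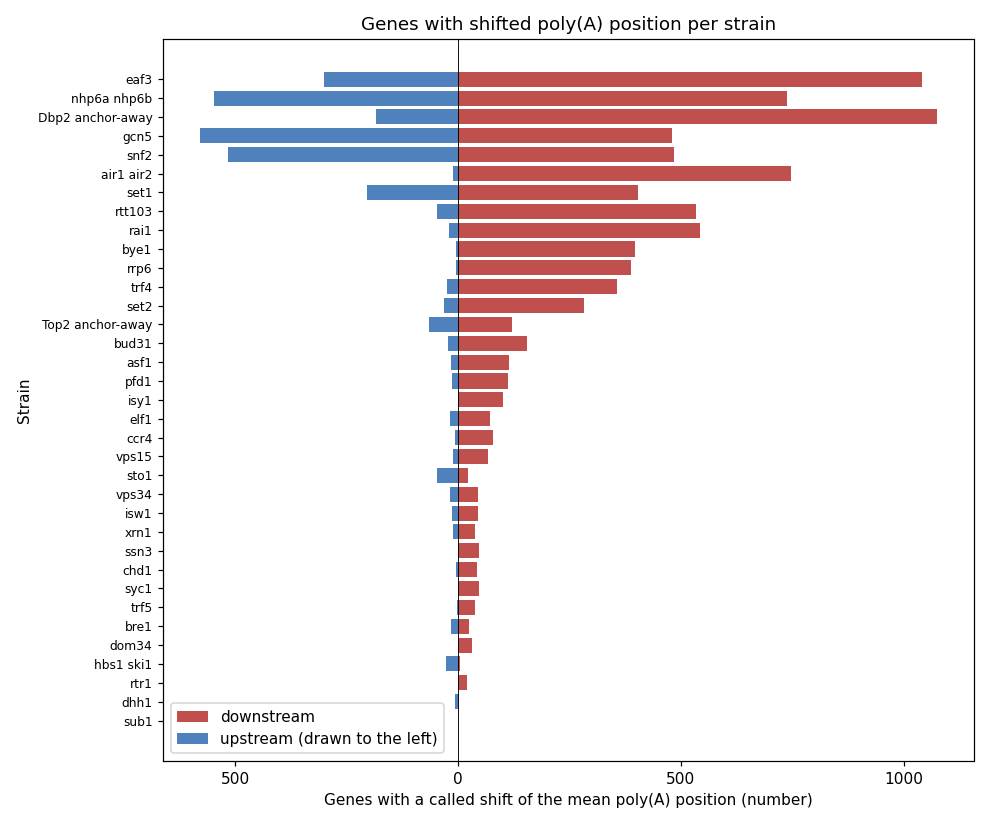
Number of genes with a shifted mean poly(A) position (x axis) for each strain (y axis), with downstream calls drawn to the right and upstream calls to the left; nhp6a nhp6b was compared with BY4741 in 1 contrast. eaf3 has 1040 downstream and 301 upstream calls, and sub1 has none.

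In eaf3, 1040 genes ended downstream and 301 upstream. RVB2, encoding an AAA ATPase of chromatin remodellers (chromosome XVI, stop codon ending at 104647), ended at 244 ± 0.460 nt (SD, n = 2) against 102 ± 29.1 nt (SD, n = 4) in JGY2000, on 24705 to 40385 reads in eaf3. HIS3, a histidine synthesis gene often used as a strain marker (chromosome XV, 722608), ended at 274 ± 0.255 nt (SD, n = 2) against 142 ± 18.1 nt (SD, n = 4), adjusted p = 2.06e-20. GAR1, a snoRNP protein gene (chromosome VIII, 282681), moved the other way by -97.2 nt, to 53.0 ± 4.01 nt (SD, n = 2). FMP30, encoding a mitochondrial phospholipase, moved by -145 nt, although its eaf3 replicates differed by an SD of 85.5 nt. Several other large shifts rest on few reads: NDD1, a cell cycle activator gene, had 1 read in each eaf3 library, SMC6, for a DNA repair complex, had 16 to 191, and BUL2, for a ubiquitin ligase adaptor, 19 to 67. The eaf3 replicates differed most of all groups relative to sampling error, and weighting each group by its own spread left 148 calls, with GAR1 no longer among them (adjusted p = 0.369).

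In the nhp6a nhp6b strain, compared with BY4741, 739 genes ended downstream and 547 upstream. RNQ1, a prion protein gene (chromosome III, 71367), ended at 247 ± 4.05 nt (SD, n = 2) against 99.1 ± 0.676 nt (SD, n = 2). IPI3, a pre-rRNA processing gene (chromosome XIV, 295960), ended at 254 ± 0.356 nt against 113 ± 0.0559 nt (SD, n = 2 each). Both genes varied widely among the JGY2000 libraries, RNQ1 at 150 ± 62.3 nt and IPI3 at 159 ± 62.3 nt (SD, n = 4 each). The 1 pair of BY4741 does not show such a spread between control pairs, so part of these shifts may not come from the deletions. RBL2, a tubulin folding gene, moved by 102 nt and CTF8, a sister chromatid cohesion gene, by 94.1 nt. APM1, a clathrin adaptor gene, moved by -79.3 nt and PUP2, a proteasome subunit gene, by -92.4 nt, both nearer the stop codon. RPS28B, a ribosomal protein gene whose protein binds its own mRNA, moved by 153 nt. TRP1, a tryptophan synthesis gene also used as a marker, moved by -71.4 nt. The median position called 761 genes.

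Dbp2 is a DEAD-box RNA helicase and Top2 the main topoisomerase of the nucleus. Nuclear depletion of Dbp2 shifted 1259 genes, 1074 downstream and 185 upstream. BAT2, a branched-chain aminotransferase gene (chromosome X, 706874), ended at 275 ± 17.0 nt (SD, n = 2) against 108 ± 16.0 nt (SD, n = 4). UBR2, a ubiquitin ligase gene, moved by -219 nt (by -13.0 nt over positions 1 to 300, adjusted p = 0.747), and PIN3, encoding a prion-forming protein, by 116 nt. MCM1, a transcription factor gene, moved by 112 nt. Top2 depletion shifted 186 genes, 120 downstream and 66 upstream; without replicate A of Top2 there were 108 and without JGY2000 2022 replicate A 113. Between the 2 anchor-away strains 1605 genes differed, 1332 of them further downstream in Dbp2 depletion, with a median of 4.00 nt. The comparison with JGY2000 also carries a strain difference: MF(ALPHA)1, a mating pheromone gene, reached 1270 and 2100 cpm in the Dbp2 and Top2 strains against 0.348 and 0.508 in the JGY2000 pairs, LEU2, a leucine synthesis gene, 298 and 249 against 0.272 and 0.359, and STE2, a pheromone receptor gene, 9.92 and 9.34 against 815 and 287. Only the anchor-away strains were given rapamycin and the JGY2000 controls were not, so the drug, the strain and the depletion cannot be told apart there. The contrast of Dbp2 with Top2 shares the background and the drug, and these marker genes were chosen after their values were seen. Variance weights left 834 Dbp2 calls and 82 Top2 calls.

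Gcn5, Snf2 and the histone methyltransferase Set1 moved genes both ways. gcn5 had 579 upstream and 479 downstream calls, snf2 517 and 485, set1 205 and 404. PUP2 (chromosome VII, 998358) moved towards the stop codon in gcn5, to 75.9 ± 8.85 nt (SD, n = 2) from 195 ± 20.2 nt (SD, n = 4). HPM1, encoding a methyltransferase of a ribosomal protein, moved by -97.7 nt, PMT6, for a protein mannosyltransferase, by -95.1 nt, and TFC6, for an RNA polymerase III factor, by -83.1 nt. BAT2 moved by 128 nt the other way, to 236 ± 27.3 nt (SD, n = 2). PHM6, a phosphate-regulated gene, moved by 113 nt on 19 to 29 reads in gcn5. RRN7, an RNA polymerase I factor gene, was the largest upstream shift in snf2 at -118 nt, but JGY2000 itself varied by an SD of 69.9 nt, and the call was lost without snf2 replicate B (adjusted p = 0.106) and without JGY2000 2018 replicate A (adjusted p = 0.123). In set1 the uncharacterised YPR071W moved by 132 nt, a call lost without JGY2000 2022 replicate A (adjusted p = 0.0524), and YLR363W-A by -106 nt, or by 1.68 nt over positions 1 to 300. Under variance weights gcn5 had 576 calls and snf2 444, and set1 had 352 without set1 replicate B.

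In the mutants of nuclear RNA decay and termination below, most called genes ended downstream. set2 (282 downstream and 32 upstream calls) and trf5 (39 and 3) leaned the same way. So did all other strains with calls except dhh1, gcn5, snf2, sto1 and the libraries labelled hbs1 ski1. JGY2000 2022 against 2018 leaned downstream too (1004 and 357). The lean is thus not particular to the mutants below, and no test set them apart from other strains. Air1, Air2 and the poly(A) polymerase Trf4 form the TRAMP complex that hands RNA to the nuclear exosome with its exonuclease Rrp6; Rai1 and Rtt103 work with the torpedo exonuclease Rat1 at terminators; Bye1 binds RNA polymerase II. air1 air2 had 746 downstream and 11 upstream calls, rtt103 533 and 48, rai1 544 and 20, bye1 398 and 4, rrp6 389 and 5, trf4 356 and 24. PRI1, a DNA primase gene (chromosome IX, 373077), ended at 120 ± 23.7 nt (SD, n = 4) in JGY2000, at 247 ± 9.22 nt (SD, n = 2) in rtt103 and at 240 ± 3.72 nt (SD, n = 2) in rai1. CMC4, a mitochondrial protein gene (chromosome XIII, 652594), moved towards its stop codon by -177 nt in air1 air2 and by -104 nt in trf4, against the trend of both strains. YOL036W, uncharacterised, moved by 194 nt in rrp6, on 4043 to 4706 reads against 434 to 783 in JGY2000. UTP6, a pre-rRNA processing gene, moved by -47.0 nt in rrp6. RPL8A, a ribosomal protein gene, moved by -95.9 nt in rai1, or by 3.16 nt over positions 1 to 300. YJL047C-A moved by 200 nt in air1 air2 and 201 nt in trf4, with an SD of 99.3 nt among the JGY2000 libraries. Without trf4 replicate A the trf4 call was lost. Its reads rose to 21058 to 23604 in air1 air2 and 14500 to 16838 in trf4, against 1111 to 2012 in JGY2000. The mean positions, 379 and 380 nt, lay near the end of the 400 nt window. CMC4 reads also rose, to 531 to 835 in air1 air2 and 557 to 807 in trf4, against 71 to 318 in JGY2000. YJL047C-A, YOL036W and CMC4 thus shifted with more reads, and whether the same transcripts moved was not tested. MRPL25, a mitochondrial ribosomal protein gene, moved by 106 nt in bye1, a call lost without bye1 replicate B (adjusted p = 0.114) and without JGY2000 2022 replicate A (adjusted p = 0.171).

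**Figure D2:**
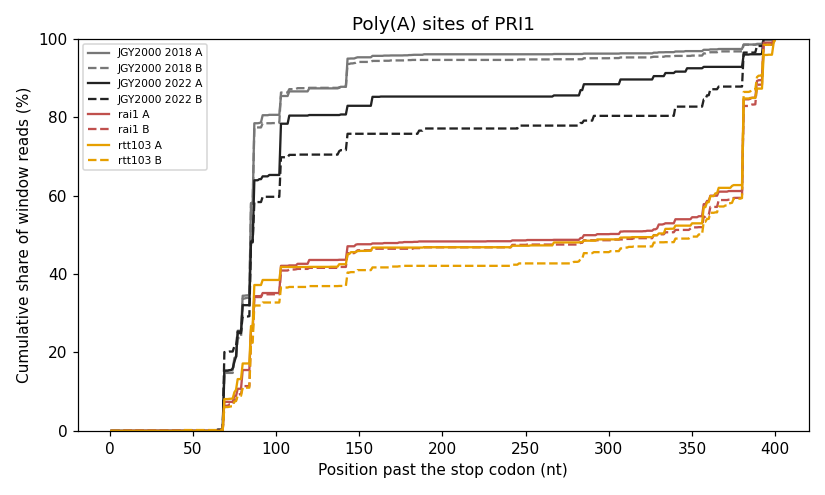
Cumulative percent of PRI1 reads (y axis) by position past the stop codon in nt (x axis) for each library of JGY2000, rai1 and rtt103. Up to 150 nt lie 75.8 to 95.3 percent of reads in JGY2000, 46.1 and 47.6 percent in rai1 and 41.0 and 45.9 percent in rtt103.

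These counts lean on single libraries. The air1 air2 count fell from 757 to 496 without replicate A, 386 without replicate B and 465 without JGY2000 2022 replicate B; the rtt103 count was 309 without replicate A, rai1 329 without replicate A and bye1 170 without replicate B. For rrp6 it was 236 without replicate A, 205 without replicate B and 245 without JGY2000 2018 replicate A, and for trf4 1.2e+02 without replicate A and 205 without JGY2000 2022 replicate B. Variance weights gave 731 calls in rrp6 and 245 in trf4.

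All genes together moved on balance downstream in 10 of 35 strains (fry), and in 9 to 12 with 1 library left out. nhp6a nhp6b was lost without its replicate A (adjusted p = 0.0967) and without BY4741 replicate A (adjusted p = 0.0769). trf5 was gained without JGY2000 2022 replicate A, where asf1 was gained too, and without either library of bye1 or of snf2 (adjusted p from 0.0161 to 0.0490). With 1 contrast against the 4 JGY2000 libraries 29 strains had a shift, 27 downstream and 2 upstream, dhh1 and the libraries labelled hbs1 ski1. The median shift over genes was 7.14 nt in air1 air2 (adjusted p = 7.89e-12), 5.32 in bye1 (adjusted p = 1.67e-07), 5.31 in rai1 (adjusted p = 8.19e-08), 5.06 in Dbp2 depletion, 4.93 in trf4, 4.19 in rrp6, 4.14 in rtt103, 3.90 in set2, 3.71 in eaf3 and 0.900 in nhp6a nhp6b. With at least 50 positions nhp6a nhp6b had no such shift, with a median of -0.005 nt (adjusted p = 0.761), the other 9 strains kept theirs, and trf5 joined them (adjusted p = 0.0207). Set2 is a histone methyltransferase that follows RNA polymerase II, and its loss gave 282 downstream and 32 upstream calls, 142 calls in all without set2 replicate A. In air1 air2 the estimated shift was downstream in 87.7 percent of genes, called or not, while 19.3 percent of genes were called. Between the JGY2000 2022 and 2018 pairs 66.7 percent of genes lay downstream. The air1 air2 median was 8.68 nt against the 2018 pair and 5.05 nt against the 2022 pair. By the median poly(A) position the shift was smaller, 1.22 nt in air1 air2, 0.825 in bye1 and 0.259 in rrp6. The libraries labelled hbs1 ski1 had the lowest median, -2.22 nt, with an adjusted p of 0.0982. Trf5, the paralog of Trf4, gave 2.38 nt with an adjusted p of 0.0718.

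**Figure D3:**
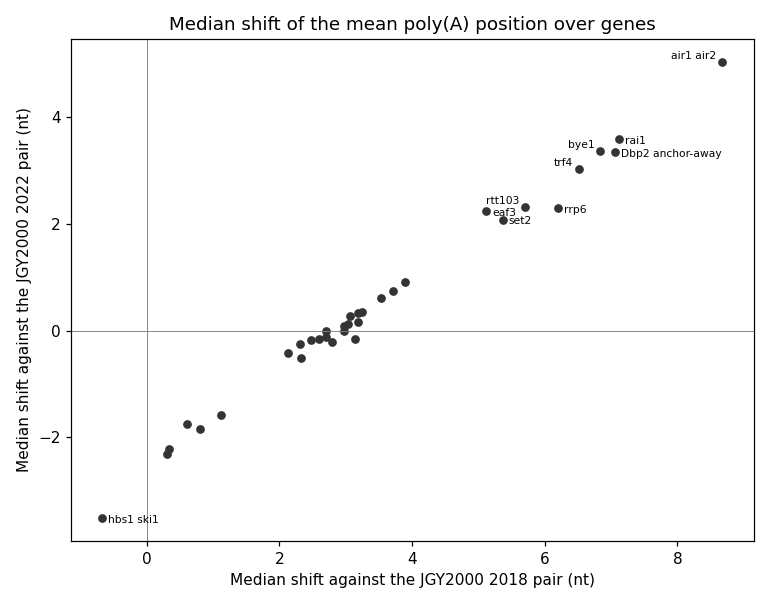
Median shift of mean poly(A) position over all tested genes in nt, against the JGY2000 2018 pair (x axis) and against the 2022 pair (y axis), with 1 point for each strain compared with JGY2000. air1 air2 lies furthest downstream at 8.68 and 5.05 nt, and the libraries labelled hbs1 ski1 furthest upstream at -0.668 and -3.52 nt.

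The remaining strains moved fewer genes. Most calls in the splicing factor strains were downstream, 155 of 178 in bud31 and all but 1 in isy1, 100 genes. Neither strain had a shift over all genes by fry (isy1 adjusted p = 0.8, bud31 mixed in direction). The lean is not particular to them, as all 16 calls of the wild-type BY4741 were downstream too. The histone chaperone strain asf1 had 115 downstream and 17 upstream calls, and elf1 72 and 19. The deadenylase strain ccr4 had 78 downstream and 8 upstream calls. Ssn3, the Mediator kinase, and Syc1, a cleavage factor subunit, gave only downstream calls, 48 and 46, as did the ribosome rescue factor Dom34 with 32. sto1, which lacks the large subunit of the nuclear cap-binding complex, was the reverse, with 48 upstream and 23 downstream calls. The libraries labelled hbs1 ski1 had 28 upstream and 4 downstream calls. Most of these counts changed by over 1.5 times without a single library: asf1 gave 31 without replicate A and 260 without replicate B, and in the same order dom34 gave 1 and 52, syc1 6 and 2, bud31 72 and 68, isy1 30 and 35, ccr4 53 and 19, sto1 18 and 26, the libraries labelled hbs1 ski1 5 and 12, and pfd1, with 125 calls, 50 and 232. Without their replicate A, elf1 gave 37 and ssn3 17. Without JGY2000 2018 replicate A, asf1 gave 86, dom34 3, syc1 0, bud31 93, isy1 33, ccr4 45, sto1 37, ssn3 23, pfd1 66 and the libraries labelled hbs1 ski1 3. Without JGY2000 2018 replicate B, dom34 gave 12, syc1 25, bud31 96, pfd1 64 and the libraries labelled hbs1 ski1 9. Without JGY2000 2022 replicate B, asf1 gave 42, dom34 18, pfd1 73 and sto1 46, and without its replicate A sto1 gave 36.

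Preset pairs of factors that share a complex or pathway were compared with all strain pairs. Over 14 preset pairs the mean correlation of shifts across 3896 genes was 0.0343, against -0.138 over all 496 pairs (permutation p = 8e-05, one-sided). The mean fell to 0.00200 without replicate B and 0.00214 with at least 50 positions (permutation p = 7e-05 and 1e-04, one-sided). With names permuted only within the 2 blocks of strains, a test chosen after the blocks were seen, the permuted mean was -0.0811 (permutation p = 1e-05, one-sided, the smallest these permutations can give). The blocks come from the same correlations and so are not independent of the test. The mean rests on 3 pairs, and the other 11 ranged from -0.405 to 0.0810. The strongest preset pair was gcn5 with snf2 at 0.508, rank 1 of all pairs. air1 air2 with trf4, both TRAMP, had 0.359 (rank 4), and rai1 with rtt103, both partners of Rat1, had 0.340 (rank 5). bud31 with isy1 had 0.0810 and trf4 with trf5 0.0759. The 2 JGY2000 pairs differ in 1361 genes, so a strain near the 2018 pair and one near the 2022 pair tend to a negative correlation by construction. A negative value, or the negative mean over all pairs, is thus no sign of opposed effects. Pairs within a block had a mean of -0.00599 and the 247 pairs between the blocks -0.270, and 4 preset pairs lay between them. Of those, the remodellers isw1 and chd1 gave -0.348 (rank 207 of 247) and xrn1 with the libraries labelled hbs1 ski1 -0.405 (rank 242). That pair was preset because SKI1 is XRN1, and the XRN1 reads in those libraries put this basis in doubt. rrp6 with air1 air2 gave -0.0169 (rank 1 of 247) and rrp6 with trf4 -0.0926 (rank 5). set1, which no preset pair joins to gcn5 or snf2, had 0.471 with gcn5 and 0.470 with snf2. By opposite replicates against different JGY2000 pairs, gcn5, set1 and snf2 correlated with each other at 0.423 to 0.470, and Dbp2 depletion, in no preset pair, at 0.403 with gcn5, 0.397 with set1 and 0.387 with snf2. Genes are not independent replicates, and each pair was read against opposite JGY2000 pairs.

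**Figure D4:**
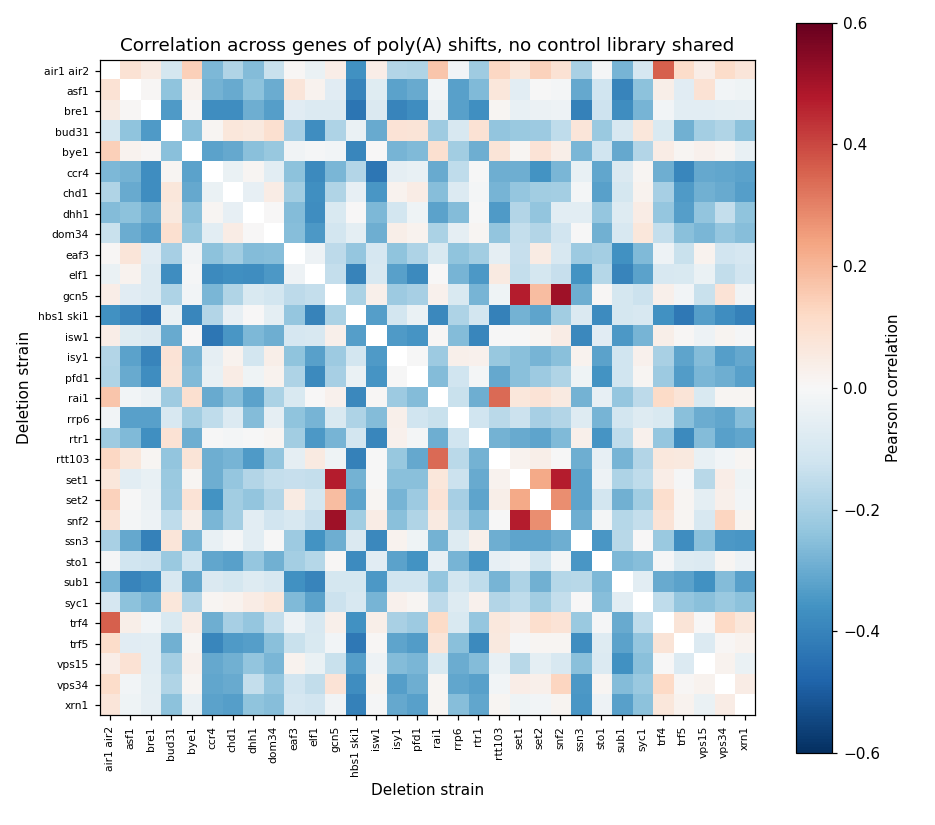
Pearson correlation of shifts across 3896 genes (colour) for each pair of the 32 deletion strains of JGY2000 (both axes), 496 pairs in all. gcn5 with snf2 lies at 0.508, and the mean of all pairs at -0.138. The difference between the JGY2000 pairs pushes values below 0 by construction.

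Some genes moved in most strains. ASH1, whose mRNA is carried to the daughter cell (chromosome XI, 96265), was called in 22 of 35 strains, each time downstream, by up to 40.8 nt in trf4. GLN1, the glutamine synthetase gene, was called downstream in 20 strains, and OM45, a mitochondrial outer membrane gene, in 19. CAF20, an inhibitor of translation initiation, was called downstream in 18 strains and CMK2, a calmodulin kinase gene, in 17. RPL20B, a ribosomal protein gene, was called in 23 strains, 20 of them upstream, with shifts from -8.34 to 5.98 nt around a JGY2000 position of 93.0 ± 0.917 nt (SD, n = 4). ZRC1, a vacuolar zinc transporter gene, went downstream in 18 strains and upstream in 4. SNU71, a splicing gene, went downstream in 15 and upstream in 3, and MOB1, a mitotic exit gene, in 16 and 1. The uncharacterised YPL229W was called downstream in 19. In all, 3296 of 3927 genes were called in at least 1 strain, 1988 of them only downstream and 565 only upstream. The strains share their JGY2000 controls, so the calls of 1 gene in several strains are not independent.

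Of the gene lists fixed in advance, none shifted apart from other genes by camera: 0 of 525 combinations of 15 lists and 35 strains passed with the estimated correlation, 1 had an unadjusted p below 0.05, and the preset correlation also gave 0, with 11 below 0.05 unadjusted. Counting called genes instead, by Fisher's exact test added after that result, 48 of 1050 tests passed. Of genes with short 3′ UTRs in gcn5, 186 of 974 were called downstream (19.1 percent against 9.92 percent of other genes, Fisher's exact adjusted p = 1.5e-10), while 214 of 974 genes with long 3′ UTRs were called upstream (22.0 against 12.4 percent). snf2 gave 187 and 184. In Dbp2 depletion 351 of 974 short 3′ UTR genes were called downstream (36.0 against 24.4 percent). Of 23 ergosterol synthesis genes in gcn5, 11 were called upstream (47.8 against 14.6 percent of other genes, Fisher's exact adjusted p = 0.00613), 2 downstream and 10 not at all, and adjusted over the list alone 14 were called in either direction. Ribosomal protein genes were called downstream in set2, 26 of 138 (18.8 against 6.79 percent), although their median shift, 2.82 nt, was below that of other genes, 3.93 nt; adjusted over the list alone 29 were called. In elf1 58 of 1814 tandem genes and 14 of 2082 convergent genes were called downstream. A gene already near the stop codon has more room to move downstream than upstream, and the UTR lists were ranked in BY4741, which is no control of these strains.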

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

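Chosen only after the result was seen were the test on low positions, the test of the 2022 pair, the comparison with blocks of strains, the test of variance weights in eaf3, the tests of the 10 genes with the largest rise of ORF reads and the test of distinct positions in gcn5, set1 and snf2; the others below were chosen before.

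Reads inside ORFs and other annotated genes, which the comparisons do not use, were above the level of the controls in 3 groups. They made up 3.52 to 5.04 percent of reads in the JGY2000 libraries (4.46 ± 0.660, SD, n = 4), 8.215 percent in the libraries labelled hbs1 ski1, 7.512 percent in rrp6 and 5.633 percent in isw1 (n = 2 each). Depth argues against itself as the cause, with a Spearman correlation of -0.03687 between ORF share and reads over 38 groups. At least 28.12 percent of genes had a higher ORF share in both libraries than in all 4 JGY2000 libraries, which left open whether a few genes take most of the ORF reads; the 10 genes that rose most carried at least 75.09 percent of the rise in rrp6, where 5 of them are not ORFs, so a few genes are a candidate cause there, but at most 9.459 percent in the libraries labelled hbs1 ski1, which argues against it. In isw1 it stays open at 33.27 percent, between the bounds of 25 and 50; these libraries were first tested as 1 set with those labelled hbs1 ski1, which stayed open, and were split at the same bounds after the values were seen.

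The strains air1 air2, bye1, rai1, rrp6, rtt103 and trf4 shifted downstream over all genes. Each kept at least 71.17 percent of its median shift with positions below 2 percent of the highest set to 0. This argues against scattered reads below that level. By the median position, which a thin tail of reads moves less, their shifts were only 0.259 nt (rrp6) to 1.22 nt (air1 air2). A tail of reads above that level thus stays open. Genes with no ORF within 400 nt shifted by at least 77.06 percent as much as the other genes in each strain, which argues against reads of a neighbour. Of the 2 blocks of strains, 5 of the 6 strains lie in that nearer the 2022 pair and rrp6 in the other. In the former, 12 of the 19 strains had no call of a shift over all genes. Their medians were at most 2.38 nt, and at most 0.921 nt against the 2022 pair (both trf5). A call needs a shift against the 2022 pair too, so a strain that only lies near that pair cannot be called. The missing calls thus cannot weigh against a block effect. With 1 contrast against the 4 JGY2000 libraries most of these 12 strains were downstream. A batch particular to the 6 strains stays open, because the labels date no strain; their median shifts against the 2022 pair ran from 2.294 nt (rrp6) to 5.05 nt (air1 air2), beside 2.76 nt between the parental pairs. Later termination or slower decay may underlie the shift, was not tested, and cannot be told apart from such a batch.

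Calls in both directions were weighed for eaf3 and for gcn5, set1 and snf2. In eaf3 few distinct molecules behind the reads are a candidate cause: at equal reads its libraries held 0.509 and 0.463 of the distinct positions of JGY2000, and weighting left 11.04 percent of the calls. In gcn5, set1 and snf2 another test argues against the same cause, for the shifts that these strains share. Shifts of opposite replicates against different JGY2000 pairs correlated across genes at 0.4227 or more in all 3 strain pairs. This does not cover each call. Variance weights, chosen after the result was seen, left 444 of 1002 calls in snf2, 576 of 1058 in gcn5 and 439 of 609 in set1. Opposite replicates of eaf3 itself correlated at 0.2872, so the 2 tests do not set eaf3 apart on 1 scale. A library batch shared by these 3 strains stays open because the labels give no dates; their distinct positions, at most 0.9444 of those of JGY2000, measure complexity, are as low in other groups and decide nothing about it. By the same correlation of opposite replicates Dbp2 depletion also resembled them, at 0.387 to 0.403, and no biological explanation was tested.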

How the results depend on the processing

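Chosen only after the result was seen were the tests with variance weights, with at least 50 reads, without the eaf3 and pfd1 libraries and with names permuted within blocks of strains; the others were planned. The number of called genes stayed within 1.5 times in every comparison with no filter on positions and with a replicate block. Replicate letters did not pair libraries across all strains: over 703 strain pairs the median correlation of the replicate differences was 0.0123. Single pairs ran from -0.317 to 0.298, with 9.39 percent over 0.1, so pairing among some strains is not excluded.

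With the median position the counts that moved by over 1.5 times were air1 air2 220, bud31 105, bye1 161, dhh1 31, gcn5 671, the libraries labelled hbs1 ski1 55, isy1 60, rai1 283, rrp6 132, rtr1 42, rtt103 239, set1 363, set2 172, snf2 636, sub1 12, trf4 133, Dbp2 689, nhp6a nhp6b 761, BY4741 61, JGY2000 2022 against 2018 806 and Dbp2 against Top2 847. Unless a cause is given, the cause was not tested. With at least 50 positions fewer genes were tested, and the counts were air1 air2 253, asf1 48, bre1 18, bud31 71, bye1 143, chd1 15, eaf3 288, elf1 33, gcn5 319, the libraries labelled hbs1 ski1 15, isw1 35, isy1 39, pfd1 38, rai1 200, rrp6 160, rtr1 13, rtt103 158, set1 197, set2 116, snf2 302, syc1 26, trf4 141, trf5 24, vps15 46, vps34 31, xrn1 22, Dbp2 321, Top2 56, nhp6a nhp6b 370, BY4741 25, JGY2000 2022 against 2018 382 and Dbp2 against Top2 419. With 1 contrast against the mean of the 4 JGY2000 libraries a gene no longer had to pass against both pairs, and the counts rose to air1 air2 2062, asf1 928, bre1 510, bud31 877, bye1 1575, ccr4 754, chd1 602, dhh1 587, dom34 597, eaf3 2307, elf1 753, gcn5 2019, the libraries labelled hbs1 ski1 660, isw1 688, isy1 790, pfd1 915, rai1 1726, rrp6 1305, rtr1 546, rtt103 1623, set1 1637, set2 1510, snf2 2006, ssn3 653, sto1 644, sub1 402, syc1 633, trf4 1616, trf5 737, vps15 832, vps34 761, xrn1 655, Dbp2 2231, Top2 963 and BY4741 562; 29 strains then had a shift over all genes, 27 downstream and 2 upstream.

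With variance weights, which change the spread assumed for each group, the counts were asf1 38, bud31 440, ccr4 288, chd1 143, dhh1 1.2e+02, eaf3 148, gcn5 576, the libraries labelled hbs1 ski1 152, isy1 346, pfd1 45, rrp6 731, rtr1 50, snf2 444, sto1 152, sub1 4, syc1 250, trf4 245, trf5 78, vps34 121, Dbp2 834, Top2 82, BY4741 145 and Dbp2 against Top2 908. Without the eaf3 and pfd1 libraries every count that moved was higher: asf1 205, bud31 274, ccr4 130, chd1 81, dhh1 15, elf1 138, the libraries labelled hbs1 ski1 51, isw1 99, isy1 167, rtr1 41, ssn3 81, sto1 113, syc1 75, trf4 574, trf5 73, vps15 129, vps34 113, xrn1 103 and BY4741 26. With at least 50 reads pfd1 had 65 calls from fewer genes, a limit set by its depth. With positions 1 to 300 rrp6 had 249 and BY4741 30, and with positions below 2 percent set to 0 rrp6 had 260 and syc1 24.

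Leaving out 1 replicate at a time assumes that the lone library left varies like the other groups. The lowest and highest counts were air1 air2 386 to 639, asf1 31 to 260, bre1 10 to 35, bud31 68 to 164, bye1 170 to 371, ccr4 19 to 80, chd1 14 to 44, dhh1 2 to 11, dom34 1 to 52, eaf3 954 to 1470, elf1 37 to 78, gcn5 728 to 1039, the libraries labelled hbs1 ski1 3 to 31, isw1 19 to 47, isy1 30 to 87, pfd1 50 to 232, rai1 329 to 491, rrp6 205 to 334, rtr1 0 to 48, rtt103 309 to 500, set1 352 to 583, set2 142 to 278, snf2 752 to 985, ssn3 17 to 44, sto1 18 to 49, sub1 0 to 1, syc1 0 to 42, trf4 1.2e+02 to 345, trf5 15 to 31, vps15 23 to 58, vps34 18 to 41, xrn1 25 to 44, Dbp2 908 to 1174, Top2 108 to 205, nhp6a nhp6b 870 to 913, BY4741 2 to 15, JGY2000 2022 against 2018 881 to 1247 and Dbp2 against Top2 1160 to 1467. The number of strains with a shift over all genes ran from 9 (without BY4741 replicate A and without nhp6a nhp6b replicate A) to 12 (without JGY2000 2022 replicate A). Without the eaf3 and pfd1 libraries, eaf3 itself left out, it was 9. That number was not computed under variance weights. With at least 50 positions nhp6a nhp6b left the 10 strains (adjusted p = 0.761) and trf5 joined them (adjusted p = 0.0207).

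The mean correlation of the preset pairs stayed above that of permuted names under every alternative run, from 0.00200 (without replicate B) to 0.0563 (Spearman), with permutation p from 1e-05, the smallest the permutations can give, to 2e-04. camera called 0 list and strain combinations under every alternative run. Of 1387 values of named genes under the alternatives, 1273 kept direction and call, 99 kept direction and lost the call, and 15 reversed. The lost calls were 29 with the median position, 26 with positions 1 to 300, 20 with variance weights and 24 without a replicate. The reversals all came with positions 1 to 300 (shift in nt), a window that leaves out sites past 300 nt: CBP6 in eaf3 -13.0, YLR363W-A in nhp6a nhp6b 2.19, RPB2 in nhp6a nhp6b 10.1, YLR036C in nhp6a nhp6b -1.17, YSP1 in Dbp2 3.86, YLR363W-A in Dbp2 4.42, BEM3 in Dbp2 6.11, SMC4 in Dbp2 25.9, SMC4 in gcn5 27.5, YSP1 in gcn5 3.06, YJL047C-A in gcn5 -1.08, AVL9 in gcn5 -6.63, PHR1 in gcn5 -4.54, YLR363W-A in set1 1.68 and RPL8A in rai1 3.16.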

Other observations

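The test of the interaction in elf1 and the tests of reads per gene were chosen only after the result was seen, as were the genes named from reads per gene; the test among elf1 genes without a close neighbour was chosen before.

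In elf1, tandem genes were called downstream more often than convergent genes, and reads of the neighbouring gene were a candidate cause. Among genes with no ORF within 400 nt the excess was no longer past the threshold: 22 of 933 tandem genes (2.36 percent) and 6 of 366 convergent genes (1.64 percent), Fisher's exact p = 0.527. That p rests on 28 calls and alone does not show that the shares are equal. With a neighbour within 400 nt it was 36 of 896 (4.02 percent) and 8 of 1731 (0.462 percent). A logistic model over genes, run after the Fisher result was known, gave p = 0.00455 for the interaction of orientation and distance. With a close neighbour the share was higher among tandem genes (4.02 against 2.36 percent) and lower among convergent genes (0.462 against 1.64 percent). Neighbouring reads, which a tandem gene shares by strand, stay a candidate cause for the tandem genes. They do not account for the lower share among convergent genes, on which the interaction also rests, so its p does not decide for this cause. Longer transcripts that run into a close neighbour were not separated from neighbouring reads.

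Reads per gene, tested with edgeR, differed in 2787 genes in nhp6a nhp6b, 2502 in gcn5, 2427 in snf2, 2244 in Dbp2 depletion, 2036 in eaf3 and 1666 in set1, and in 6 in sub1. JGY2000 2022 and 2018 differed in 2565. That count and the one of nhp6a nhp6b come from 1 contrast, an easier rule than that of both JGY2000 pairs, so they do not rank with the others. PHO84, the phosphate transporter gene, was at 5.92 ± 1.10 cpm in gcn5 and 0.624 ± 0.538 in snf2 (SD, n = 2 each), against 615 ± 262 in JGY2000 (SD, n = 4), and was also called lower in air1 air2 and nhp6a nhp6b. HSP12, a membrane stress protein gene, was called higher in 23 of 35 strains, at 2.55 cpm (set1) to 136 cpm (Dbp2 depletion). The low end is few reads, with sub1, not called, at 0.295 cpm. The calls followed the blocks of strains. Every strain of the block nearer the 2022 pair was called except bre1 and trf5. Of the other block only bud31, ccr4 and ssn3 were. Of 34 general stress genes 18 were higher in ssn3, 17 in Top2 depletion, 12 in Dbp2 depletion and 11 in isw1. In ccr4, 29 of 35 oxidative phosphorylation genes were higher, with a median log2 change of 1.42. The change is not special to ccr4: 29 of 35 were also higher in Top2 depletion (median 1.73) and 28 in Dbp2 depletion (median 1.82). FLX1, a mitochondrial carrier gene, was at 730 ± 32.3 cpm in rrp6 (SD, n = 2) against 9.96 ± 2.40 (SD, n = 4), with higher calls also in eaf3 (56.5) and air1 air2 (23.2). UTP6 was at 32.0 ± 0.207 in rrp6 against 419 ± 291, so its shift of -47.0 nt came with fewer reads. It was also called lower in chd1, dom34 and ssn3 and higher in nhp6a nhp6b (515 cpm, against BY4741). UTP6 followed the 2 blocks of strains. The 13 strains nearer the 2018 pair, with rrp6 the lowest, chd1 next at 77.6 and sub1 the highest, lay at 32.0 to 164 cpm. The other 19 lay at 275 (eaf3) to 936 (air1 air2). The lower calls all fell in the former block, so block and deletion are not told apart there. In nhp6a nhp6b 37 of 63 ribosome biogenesis genes were higher, and 20 of 30 chaperone and 6 of 10 histone genes lower; in snf2 7 of 10 histone genes were lower. Of 138 ribosomal protein genes 57 were lower and 24 higher in snf2, 55 and 15 in eaf3, 54 and 5 in air1 air2, 48 and 0 in vps34, 45 and 31 in nhp6a nhp6b, 38 and 50 in gcn5 and 16 and 55 in set1. These list counts were not tested for enrichment.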
